A study of Homo sapiens and Homo sapiens
Mus musculus with 28 samples.

How the data were processed

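Data came from U2OS cells in 28 samples: RNA-seq (4), MYC ChIP-seq (4), H3K27ac ChIP-seq (4), ChIP inputs (4), 4C-seq (4) and spike-in Hi-C with mouse NIH3T3 cells (8, of which 4 also had siRNA for 48 h). Groups were taken from the sample titles and treatments: vehicle (low MYC) or 1 µg/ml doxycycline for 30 h (high MYC). The Hi-C samples and inputs were not analysed here.

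For RNA, the authors deposited estimated counts, TPM and effective lengths per RefSeq transcript, made with kallisto (version not given in the sources used here) per the submitters' processing notes. The protocol in the labels names ribosomal RNA depletion and a stranded kit. For ChIP, the authors deposited peak lists holding the fold enrichment and the -log10 q-value of each peak, made with BWA 0.7.5a-r405 and MACS2 2.1.2 on build hg19 per the submitters' processing notes, with 1 list for both replicates of a group per the labels. For 4C, the authors deposited the read count, a signal value and a q-value per 5 kb window, with 1 table for both replicates of a group; the caller is not given in the sources used here. The signal column was not used in any comparison, because it is a function of the count column in each table. The notes also name SAMtools 1.7, bedtools 2.26.0, deepTools 3.2.1, Juicer and build mm10.

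Transcripts were summed to genes through the RefSeq accessions of GRCh38.p14, used for names alone: 71707 of 72366 transcripts (99.1%) matched a symbol, and 28589 features resulted. The 659 unmatched transcripts, 0.35 to 0.43% of counts, were kept under their own identifiers. The signal recognition particle RNAs RN7SL1, RN7SL2 and RN7SL3 took 19.3, 16.6, 18.7 and 15.0% of counts in low MYC replicates 1 and 2 and high MYC replicates 1 and 2. Summed estimated counts were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3 (filterByExpr, TMM factors, quasi-likelihood F test, Benjamini-Hochberg adjustment, threshold 0.05, no replicate block). "Rose" and "fell" refer to genes past that threshold. CPM values are counts divided by the TMM-scaled library size and given per 1e6 counts.

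Tested on simulated counts for the 20536 genes of this comparison, the fit called 0 of 50 genes changed 1.25-fold, 16 of 50 changed 1.5-fold, 33 of 50 changed 2-fold and 46 of 50 changed 4-fold, with 10 false calls. Only 50 genes per fold were changed there, while 42% of genes passed in the data. The adjusted threshold was therefore stricter in the simulation, and its rates may understate those for the data. Replicates within each condition differed by more than sampling noise (chi-square per gene 74.4 and 68.3).

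Of 38 gene lists fixed before the data were examined, 37 had at least 5 tested members. They were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset inter-gene correlation of 0.01, with an estimated correlation and with fry as alternatives. With an estimated correlation, camera rests on the few residual degrees of freedom of 4 libraries, so hardly any list could pass after adjustment. Lists with an estimate under the preset lost their call too: translation initiation factors (-0.003) went from a camera p of 1.07e-05 to 0.0392 before adjustment. Other estimates lay far above the preset, such as 0.818 for ribosomal proteins, 0.732 for oxidative phosphorylation and 0.556 for ribosome biogenesis. For such lists the p-values with the preset may be too small. The list of genes of the mitochondrial genome had no member in the files.

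The genes named were chosen by a rule fixed before the data were examined. It takes MYC and the members of the MYC network list past the threshold. It takes the 8 largest rises and 8 largest falls among genes with a symbol, an adjusted p under 0.05, at least 5 CPM in the higher group and no overlap between groups. It takes the 3 members with the smallest adjusted p in the direction of each list past camera, and up to 2 members of other lists. It also takes the 5 peaks of highest fold enrichment in each MYC list and among those found in high MYC alone, and the 5 called 4C windows with the most reads over 100 kb from the viewpoint in each table. Not every gene that the rule takes is printed. Any other named feature is said to have been chosen after its values were seen.

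Peak lists were compared by overlap of at least 1 bp with Python 3.11.15, NumPy and SciPy. Chance overlap was described with 1000 circular shifts within each chromosome. Shares have exact Clopper-Pearson 95% intervals. Super-enhancer-like clusters were H3K27ac peaks stitched at a fixed distance, ranked by summed fold enrichment times width and split where the scaled rank curve has slope 1. Such clusters rest on called peaks and not on reads, so they only approximate the usual definition. The overlap code was tested on simulated intervals.

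The alternatives tried were other normalizations (RLE factors, library totals), other count filters, a replicate block, leaving out each library, transcript length offsets, DESeq2 1.42.0, limma on log2(TPM + 1) for genes with a mean TPM of at least 1, other peak thresholds and overlaps, equal list lengths, other stitching and ranking, and other 4C thresholds and ranges. Restriction to protein-coding genes and equal MYC list lengths for the clusters were chosen after seeing the data. The planned comparison of genes with a MYC peak at the promoter was not run, since no hg19 gene annotation was used here.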

Results

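The series measured what happens in U2OS cells, a human osteosarcoma line, when the transcription factor MYC is raised from a doxycycline-inducible gene. Cells received vehicle (low MYC) or 1 µg/ml doxycycline for 30 h (high MYC), with 2 biological replicates per group according to the design text. No group received doxycycline without the rise of MYC. Effects of the drug itself therefore cannot be told apart from those of MYC in any comparison below. RNA was sequenced in 4 libraries, which held 136014658 and 114815942 estimated counts in low MYC and 152831706 and 141170970 in high MYC. ChIP-seq for MYC and for H3K27ac, a histone mark of active promoters and enhancers, gave 1 pooled peak list per condition. 4C-seq, which maps the contacts of a chosen genomic viewpoint, gave 1 pooled table per condition. The spike-in Hi-C samples (8) and the ChIP inputs (4) were not analysed here.

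The induction was visible in the RNA of both high MYC libraries. MYC stood at 200 ± 39.7 CPM (counts scaled to a common library size) in low MYC and at 7353 ± 1310 in high MYC (mean ± SD, n = 2 each), a log2 fold change of 5.20 (SE 0.20, edgeR adjusted p = 7.79e-05). The rise came from transcript NM_002467, whose estimated counts went from 21356 and 26111 to 906926 and 1152280. The other listed MYC transcript, NM_001354870, had estimated counts of 1893 and 2611 in low MYC and of 819 and 1524 in high MYC. MYC alone took 0.017% and 0.025% of all estimated counts in low MYC, and 0.594% and 0.817% in high MYC.

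Of 20536 genes tested, 8619 (42.0%) changed at an adjusted p under 0.05 in edgeR's quasi-likelihood test. Of these, 4768 were higher and 3851 lower in high MYC. At least a doubling was seen for 974 genes and at least a halving for 1531. With library totals as the sole scaling, which shifted the median log2 fold change of all genes from -0.01 to -0.14, the split was 3157 higher and 4620 lower. The count of changed genes was 5591 without high MYC replicate 1, 5062 without high MYC replicate 2 and 1990 with limma on log2(TPM + 1).

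The largest rises after that of MYC were as follows. CAMKV, a pseudokinase related to calmodulin kinases, went from 4.16 ± 0.73 to 75.8 ± 2.93 CPM (log2 fold change 4.19, SE 0.14, adjusted p = 7.79e-05). PDE1B, a calmodulin-dependent phosphodiesterase, went from 3.38 ± 0.30 to 44.4 ± 5.63 (log2 fold change 3.72). RGS16, a regulator of G-protein signalling, rose by 3.49 on the log2 scale and PCDH15, a protocadherin, by 3.48. OPRL1 (the nociceptin receptor, 4.10), NTRK2 (the BDNF receptor, 3.90) and HES7 (a bHLH repressor, 3.71) started below 1 CPM in low MYC. These names come from a rule of size and not from a test for a theme.

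**Figure D1:**
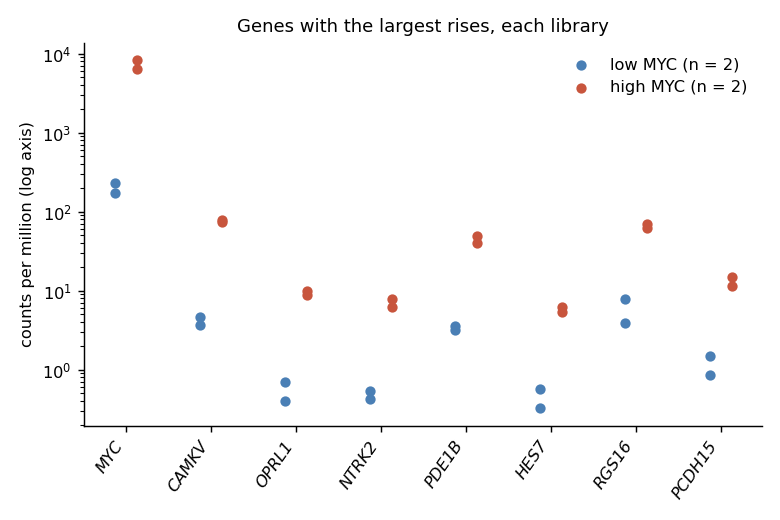
CPM (log axis) of the 8 genes with the largest rises, one point per library (2 low MYC in blue, 2 high MYC in red). In each gene both high MYC libraries lie above both low MYC ones, and MYC reaches 6426 and 8279 CPM in high MYC.

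The largest falls were chosen by the same rule of size. LBH, a transcriptional cofactor, went from 74.4 ± 21.99 to 9.82 ± 1.07 CPM (log2 fold change -2.92, SE 0.20, adjusted p = 0.000207). OLFML3, a secreted matrix protein, went from 25.6 ± 2.76 to 3.89 ± 0.01 (log2 fold change -2.72). IGFBP5, which binds insulin-like growth factors, had a value of -3.39. The cyclin CCNG2 (-2.83), the collagen COL8A1 (-2.75), the glycosyltransferase GALNT15 (-2.73) and the adhesion molecule CADM3 (-2.68) were also among them.

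Genes of ribosome production rose together. Of 56 tested ribosome biogenesis genes, 54 rose and 0 fell (54 and 0 adjusted over the list alone), with a median log2 fold change of 0.94. RRP9, a component of the small-subunit processome, rose by 1.86, POLR1B, a subunit of RNA polymerase I, by 1.24 and WDR74 by 1.27 on the log2 scale. In limma's camera test with the preset correlation the list stood apart from other genes (adjusted p = 1.17e-17). It did not pass with an estimated correlation (adjusted p = 0.489), and that estimate, 0.556, lay far above the preset of 0.01. In that setting 4 libraries leave camera little power for any list. Established MYC targets, a list fixed from textbook knowledge that shares genes with the previous one, had 39 that rose and 1 that fell among 43 (40 and 1 adjusted over the list alone), with a median of 0.89. RPIA, an enzyme of the pentose phosphate pathway, rose by 1.56. The camera adjusted p was 3.56e-12, and the adjusted p = 0.448 with an estimated correlation.

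The mitochondrial and cytoplasmic protein-making and folding machinery moved the same way. Among 36 mitochondrial ribosome genes 31 rose and 0 fell (32 and 0 adjusted over the list alone; median 0.62), with MRPS30 at 1.27, MRPS26 at 1.06 and MRPS23 at 0.95. Among 26 chaperones 22 rose and 1 fell (22 and 1 over the list alone; median 0.54). DNAJC2, a ribosome-associated chaperone, rose by 1.12, and the mitochondrial chaperonin pair HSPD1 and HSPE1 by 0.89 and 0.81. All but 3 of 20 aminoacyl-tRNA synthetases rose, 17 on either adjustment (median 0.53), with FARSA at 0.99, KARS1 at 0.73 and GARS1 at 0.61. The list of translation initiation factors had 21 of 25 that rose on either adjustment (median 0.40), among them EIF3B (0.84) and EIF2S1 (0.75). Its member EIF4EBP1, which is a repressor of initiation and not an initiation factor, rose by 0.92. Camera adjusted p-values for these lists were 2.08e-09, 2.4e-06, 4.96e-05 and 4.96e-05, and the adjusted p = 0.448 with an estimated correlation for each of them.

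Of 54 cytoplasmic ribosomal protein genes 19 rose and 0 fell (18 and 0 adjusted over the list alone), with a median of 0.20. RPS15 (0.43), RPL27 (0.41) and RPL14 (0.41) had the smallest adjusted p-values. Oxidative phosphorylation had 19 of 33 that rose and 0 that fell (20 and 0 over the list alone; median 0.34), with SDHB at 0.70, COX5A at 0.55 and UQCRFS1 at 0.53. Camera adjusted p-values were 0.00168 and 0.000232, against adjusted p-values of 0.837 and 0.724 with estimated correlations of 0.818 and 0.732. Without low MYC replicate 2 the ribosomal protein list no longer passed camera.

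Nucleotide synthesis and the integrated stress response list were also higher. Of 25 nucleotide synthesis genes 15 rose and 5 fell (17 and 5 adjusted over the list alone; median 0.53, mean 0.42). DCTPP1 rose by 1.28, IMPDH1, the first enzyme committed to guanine nucleotides, by 1.26 and PPAT, the first of purine synthesis, by 1.16. Of 24 integrated stress response genes 17 rose and 1 fell (17 and 2 over the list alone; median 0.78). TRIB3, an ATF4 target, rose by 1.28, VLDLR by 0.99 and ASNS, asparagine synthetase, by 0.84. Camera adjusted p-values were 0.00241 and 5.71e-05, and the adjusted p = 0.448 with an estimated correlation for both.

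Lower in high MYC were the genes that build the extracellular matrix and attach the cell to it. Of 37 extracellular matrix genes 24 fell and 1 rose (26 and 1 adjusted over the list alone), with a median log2 fold change of -0.81. FN1, fibronectin, went from 96.4 ± 12.47 to 28.5 ± 0.88 CPM (log2 fold change -1.76), and COL3A1 had a value of -1.76 too. Of 32 adhesion and actin cytoskeleton genes 21 fell and 0 rose (22 and 0 over the list alone; median -0.46). CAV1, caveolin-1 (-1.65), LAMB3, a laminin chain (-1.64), and TPM1, tropomyosin (-1.34), led that list. Camera adjusted p-values were 2.4e-06 and 1.42e-05, and the adjusted p = 0.448 with an estimated correlation for both. The epithelial markers, a check for other cell types, had 5 that fell and 1 that rose among 13 (6 and 1 over the list alone, median -0.85). Among them were CLDN4 at -2.65, KRT8 at -0.90 and CLDN7, under 1 CPM in both conditions, at -2.03. The camera adjusted p was 0.0249 and the adjusted p = 0.448 with an estimated correlation; without low MYC replicate 2, or with a filter at 1 CPM, this list did not pass.

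Interferon response and mitosis genes were lower as well. Of 26 interferon response genes 16 fell and 1 rose (17 and 1 adjusted over the list alone; median -0.81). IFIT1 had a log2 fold change of -2.03, STAT2, a subunit of the interferon-activated transcription factor, of -1.06, and OAS3 of -0.91. Of 33 mitosis genes 17 fell and 2 rose (19 and 2 over the list alone; median -0.26). The phosphatase CDC25C had a value of -1.06, topoisomerase TOP2A of -0.69 and the spindle kinesin KIF11 of -0.59. Camera adjusted p-values were 0.00146 and 0.00168, and adjusted p-values 0.555 and 0.513 with an estimated correlation.

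**Figure D2:**
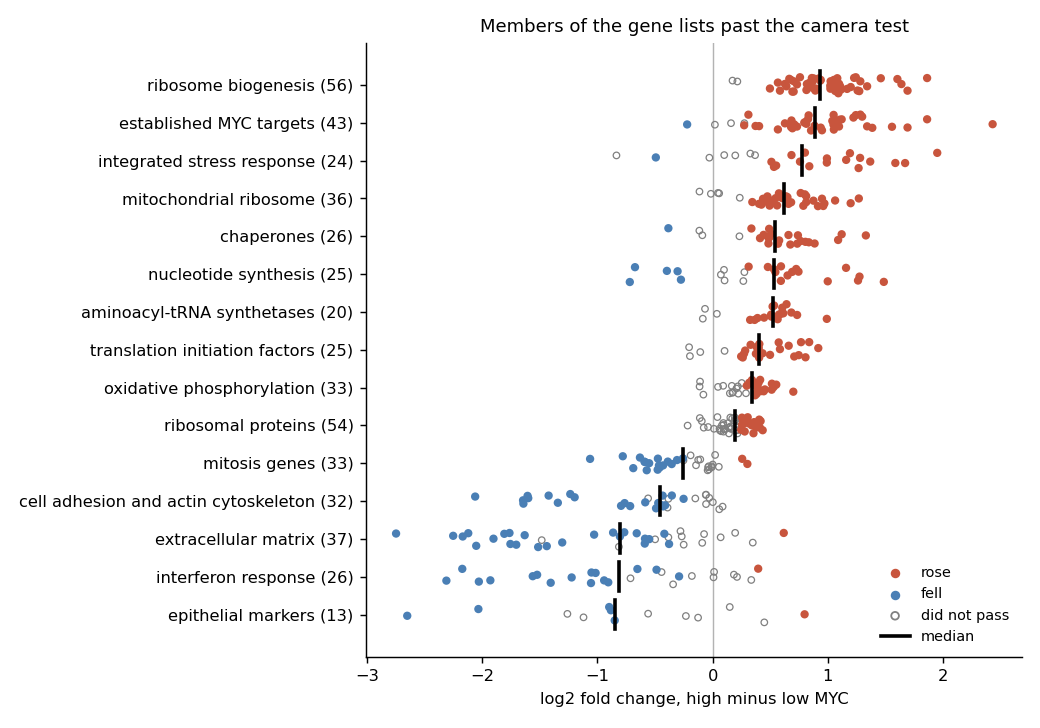
Log2 fold change (high minus low MYC) of every tested member of the 15 gene lists past the camera test, one point per gene, with the number of members in brackets. Filled points passed edgeR's test, open points did not, and black bars are list medians, which run from 0.94 for ribosome biogenesis to -0.85 for epithelial markers.

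The MYC network list holds MYC itself, whose rise the treatment sets, so its list test (camera adjusted p = 0.0626) is not a test of the other members. Of its 13 tested members 8 rose, MYC among them, and 3 fell, on either adjustment. MAX, the obligate partner of MYC, rose by 1.18 on the log2 scale and MYCL by 2.05. MGA (0.56), MXI1 (0.68), MNT (0.71), MLXIP (0.61) and MLX (0.42) rose too. MXD3 and MXD4 had values of -1.65 and -1.10, and MYCN, under 1 CPM in both conditions, -2.83.

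Of the 37 lists tested, 15 passed camera and 22 did not. Among those that did not, cell cycle genes went both ways. CDC25A (1.12) and CCNE1 (0.98) rose among 41 DNA replication and E2F genes, of which 13 rose and 8 fell. Of 13 inhibitors and cyclins of the G1 phase 3 rose and 5 fell, with the inhibitor CDKN2C at -2.31 and cyclin CCND1 at 1.07. ODC1, the rate-limiting enzyme of polyamine synthesis, rose from 350 ± 68.2 to 916 ± 85.7 CPM, while 5 of the 10 polyamine genes rose and 1 fell. Among 24 glycolysis genes 10 rose and 5 fell, with the lactate transporter SLC16A1 at 1.19 and PFKFB3 at 1.12. Among 18 CTCF and cohesin genes 4 rose and 3 fell. SMC1A had a value of -0.42 and ZNF143 of 0.47, while CTCF, chosen after its values were seen, had a value of -0.07 (adjusted p = 0.464). The camera adjusted p was 0.229 for glycolysis and 0.435 to 0.911 for the other 4 of these lists.

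Of 12 osteoblast and bone genes 1 rose, BMP2 at 1.73, and 5 fell, among them SPARC, osteonectin, at -0.86 (camera adjusted p = 0.0733). This list did pass without high MYC replicate 1, and with fry (adjusted p = 0.037), which does not compare a list with other genes. Of 19 TGF-beta and SMAD targets 3 rose and 7 fell, with LTBP2 at -1.52 (camera adjusted p = 0.229; fry adjusted p = 0.033). Of 24 p53 targets 7 rose and 7 fell, with TP53I3 at -1.06 and DDB2 at -0.97 (camera adjusted p = 0.985). Of 26 lysosome and autophagy genes 4 rose and 12 fell, with NPC2, a cholesterol carrier, at -1.81 and UVRAG at 0.86 (camera adjusted p = 0.157), and this list passed without low MYC replicate 2. Markers of other cell types that did not pass were the blood (2 of 7 fell), endothelial (1 rose and 1 fell of 10) and neural lists (1 rose and 3 fell of 12).

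For MYC binding, the pooled lists held 7458 MYC peaks in low MYC and 11911 in high MYC, a ratio of 1.60. Most low MYC peaks stayed in place: 75.9% of them (5661, exact 95% interval 74.9 to 76.9%) overlapped a high MYC peak by at least 1 bp. Conversely 46.7% of high MYC peaks (45.8 to 47.6%) overlapped a low MYC peak, which left 6349 found in high MYC alone and 1797 in low MYC alone. Intervals here and below cover counting error only, and with 1 pooled list per condition no difference has a replicate check. Where only peaks with a -log10 q of at least 10 were tested, 98.0% of low MYC and 76.1% of high MYC peaks had a counterpart.

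The strongest MYC peaks were shared. By the authors' fold enrichment, a value of each peak within its own list, the top peak of both lists lay on chromosome 7, at 4681357 to 4682086 in low MYC (64.3-fold) and 4681389 to 4682146 in high MYC (34.8-fold; all positions hg19). The next lay on chromosome 19, at 1863865 to 1864704 in low MYC (37.6-fold) and 1863705 to 1864608 in high MYC (31.9-fold). The low MYC list went on with chromosome 20, 17948879 to 17949684 (33.8-fold), chromosome 15, 68132382 to 68132632 (27.3-fold), and chromosome 17, 49243608 to 49244640 (26.8-fold). The high MYC list went on with chromosome 17, 7210849 to 7211944 (31.2-fold), chromosome 2, 74211551 to 74212503 (27.5-fold), and chromosome 1, 43148159 to 43149144 (26.1-fold). Peaks found in high MYC alone were weaker and narrower, with a median fold enrichment of 3.12 and width of 279 bp, against 4.55 and 517 bp for high MYC peaks also found in low MYC. Their highest value was 10.9-fold on chromosome 16 at 19178913 to 19179297. The next were on chromosome 17 at 7340115 to 7340644 (8.76-fold), chromosome 1 at 214560214 to 214560542 (8.19-fold), chromosome 19 at 343133 to 343566 (7.80-fold) and chromosome 5 at 71679193 to 71679471 (7.73-fold). No gene annotation of build hg19 was used here, so genes are not given for these peaks.

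The H3K27ac peak list was not longer in high MYC. The lists held 80044 peaks in low MYC and 78276 in high MYC, a ratio of 0.98, covering 79.9 and 65.2 Mb. At a -log10 q of at least 10 there were 36985 and 31236 peaks. Read depths of these libraries were not analysed here, so a change in acetylation cannot be told apart from depth or ChIP efficiency. Of the low MYC peaks 66.6% (exact 95% interval 66.3 to 66.9%) overlapped a high MYC peak, and of the high MYC peaks 74.9% (74.6 to 75.2%) overlapped a low MYC one.

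MYC peaks sat mostly in acetylated chromatin. In low MYC 75.6% of MYC peaks (74.6 to 76.6%) overlapped an H3K27ac region of that condition, and in high MYC 80.2% (79.5 to 80.9%). Randomly shifted MYC peaks overlapped in 3.95% and 3.53% of cases on average, with highest values of 4.77% and 4.24% among 1000 shifts. Of the peaks found in high MYC alone, 61.6% (60.4 to 62.8%) lay in regions already listed for H3K27ac in low MYC. That share was 90.6% (89.8 to 91.4%) for high MYC peaks also found in low MYC and 33.7% (31.5 to 35.9%) for those found in low MYC alone.

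The series title asks about super-enhancers, large clusters of enhancers. Clusters were rebuilt from the H3K27ac peak lists and are therefore called super-enhancer-like. There were 1823 in low MYC and 1674 in high MYC, with median spans of 20.4 and 16.9 kb, and 1245 of the low MYC clusters (68.3%) overlapped a high MYC one. A MYC peak lay in 36.1% of them in low MYC (33.9 to 38.4%) and in 62.8% in high MYC (60.5 to 65.2%). In the other clusters the shares were 12.3% and 19.4%. Super-enhancer-like clusters are larger by the way they are chosen and so have more chances to hold a peak. No share matched for size was computed, so this contrast does not show a preference of MYC for them. When the 1823 low MYC clusters were held fixed, 49.6% (47.3 to 51.9%) held a peak of the longer high MYC list. When both MYC lists were cut to the same length, 52.3% of high MYC clusters held a peak, an alternative chosen after seeing the data.

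**Figure D3:**
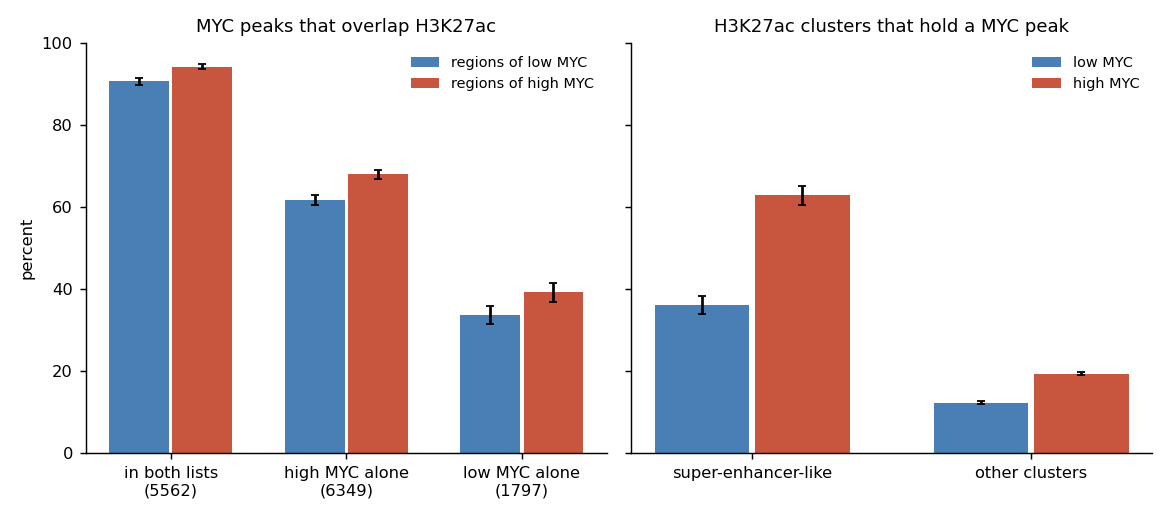
Left, percent of MYC peaks in each class (number of peaks in brackets) that overlap H3K27ac regions of low or high MYC; right, percent of super-enhancer-like and other H3K27ac clusters that hold a MYC peak. Bars are percentages with exact 95% binomial intervals, and super-enhancer-like clusters with a MYC peak go from 36.1% to 62.8%.

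One region of H3K27ac stood out, chosen after its values were seen: the peak with the highest -log10 q of the whole high MYC list, 3950, lay on chromosome 8 at 128750509 to 128751265, where the MYC gene is located. Its fold enrichment was 15.8 in the high MYC list, and the low MYC list held a peak with the same start and end at 2.58. A second narrow peak lay at 128752641 to 128753205 in high MYC (6.70-fold) and at 128752651 to 128753156 in low MYC (3.03-fold). The peak just upstream had 2.77 in the low MYC list (128747149 to 128749987) and 2.30 in the high MYC list (128747855 to 128748404). Downstream, the low MYC list held peaks of 13.7 (128766210 to 128770972) and 8.20 (128771839 to 128773785), its highest within 25 kb, and the high MYC list held peaks of 9.61 (128766371 to 128770433) and 4.88 (128772236 to 128773716). No peak of either MYC ChIP list lay within 25 kb. Both lists rest on 1 pooled call each, and fold enrichments of separate lists are not on a common scale.

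**Figure D4:**
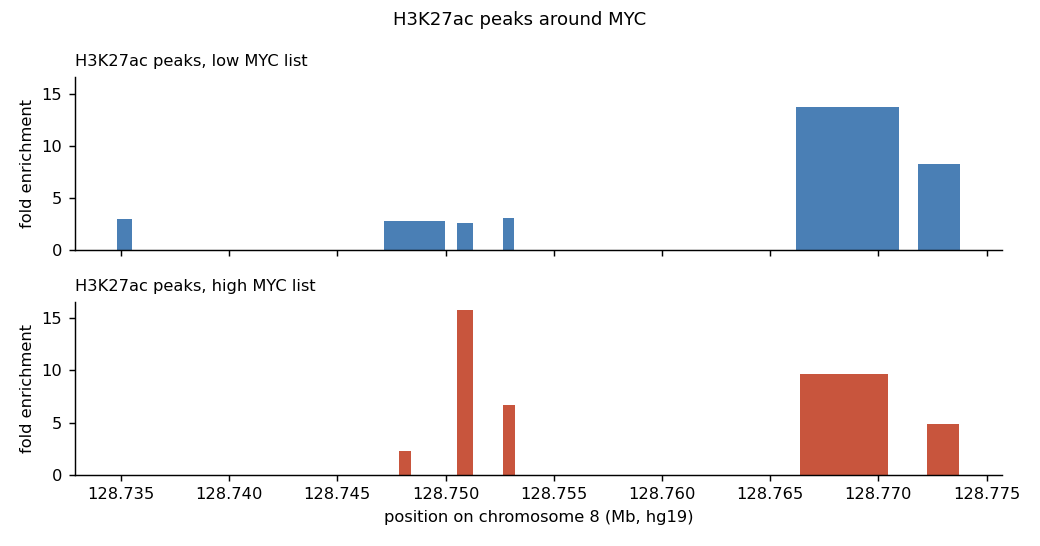
H3K27ac peaks within 25 kb of the peak with the highest -log10 q in high MYC, on chromosome 8 (position in Mb, hg19), for the low MYC list above and the high MYC list below. Each bar spans 1 peak and its height is the authors' fold enrichment, which is 15.8 for the tallest narrow high MYC peak and 2.58 for the low MYC peak with the same edges.

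The 4C tables list 5 kb windows with their reads, 68162 windows and 4741530 reads in low MYC and 84096 windows and 6045119 reads in high MYC. The viewpoint is not named in the labels. It was inferred from the 2 windows with the most reads, at 128170001 and 128190001 on chromosome 2, between which the high MYC table lists a window of PROC (1 read), the gene of the anticoagulant protein C. Chromosome 2 took 28.2% of reads in low MYC and 24.1% in high MYC, and 8.87% and 6.72% lay within 1 Mb of the inferred viewpoint. At a q under 0.05, 81 windows were called in low MYC and 113 in high MYC, 54 of them in both. On chromosome 2 the counts were 36 and 43, of which 33 were shared.

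Called contacts reached the neighbouring genes on both sides. Among windows more than 100 kb away, those with the most reads in low MYC were at CYP27C1 (127950001 to 127955000, 5128 reads), MAP3K2 (128055001 to 128060000, 5043 reads), SFT2D3 and WDR33 (128460001 to 128465000, 4744 reads) and ERCC3 (128030001 to 128035000, 4741 reads). A window with no listed gene at 92315001 to 92320000, far from these genes (-35865 kb from the inferred viewpoint), had 4961 reads in low MYC and 5605 in high MYC. In high MYC the ERCC3 window led with 7371 reads (q = 7.87e-48, against 7.12e-08 in low MYC). It was followed by a window in MYO7B (128335001 to 128340000) with 6478 reads. Next came one with no listed gene at 92325001 to 92330000 (-35855 kb) with 6328, and the CYP27C1 window had 5138. For both windows with no listed gene, repeat sequence that collects reads was not tested as an explanation. As a share of reads within 1 Mb, the MYO7B window went from 0.695% (exact 95% interval 0.67 to 0.72%) to 1.59% (1.56 to 1.63%), and was not called in low MYC (q = 0.843). Other MYO7B windows went both ways: those at 128305001 (0.748% to 0.923%) and 128360001 (0.586% to 0.958%) were also called in high MYC alone, the one at 128375001 (0.865% to 0.441%) in low MYC alone, and the one at 128320001 in both. The ERCC3 window went from 1.13% (1.09 to 1.16%) to 1.81% (1.77 to 1.86%). Other ERCC3 windows went both ways, such as the one at 128040001 (0.973% to 1.21%) and the one at 128045001 (0.418% to 0.17%). Over the same range the MAP3K2 window at 128055001 went from 1.20% to 0.93% and the SFT2D3 and WDR33 window from 1.13% to 0.932%. The CYP27C1 window had 1.22% and 1.26%. Other MAP3K2 windows went the other way, such as those at 128065001 (0.7% to 0.812%, called in high MYC alone) and 128095001 (2.49% to 3.00%). Other windows of WDR33 and CYP27C1 went both ways. PCR reads are not independent molecules, and no replicate check is possible with 1 table per condition.

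In the RNA, ERCC3, a helicase of the repair and transcription factor TFIIH, rose by 0.65 on the log2 scale (adjusted p = 0.000731). MYO7B did not pass (log2 fold change -0.46, adjusted p = 0.202), nor did MAP3K2 (0.09, adjusted p = 0.402) or WDR33 (0.11, adjusted p = 0.282). IWS1, some of whose windows were called in both tables, had a value of 0.26 (adjusted p = 0.0258), and CYP27C1 of -1.02 (adjusted p = 0.0392). These genes were chosen after their 4C values were seen.

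**Figure D5:**
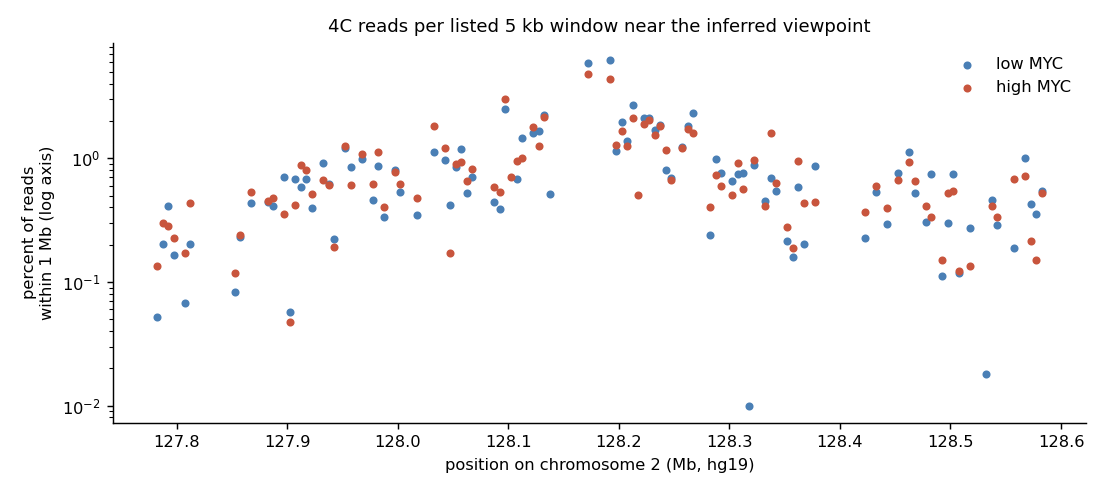
Percent of the 4C reads within 1 Mb of the inferred viewpoint (log axis) in each listed 5 kb window on chromosome 2 (window centre in Mb, hg19), low MYC in blue and high MYC in red, for windows within 400 kb that hold at least 0.01% of those reads. Each point is 1 window of 1 pooled table, and the MYO7B window is at 0.695% in low MYC and 1.59% in high MYC.

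The called 4C windows did not lie at MYC peaks more often than chance placement could give. A MYC peak of the same condition lay in 2 of 81 called windows in low MYC (2.5%, exact 95% interval 0.3 to 8.6%) and in 2 of 113 in high MYC (1.8%, 0.2 to 6.2%). Random shifts gave 1.3% and 1.9% on average. An H3K27ac region lay in 17.3% (9.8 to 27.3%) and 16.8% (10.4 to 25%), against 11.8% and 12% under shifts, whose central 95% reached from 3.7 to 22.2% and from 4.4 to 19.5%. With so few called windows the intervals leave room for a modest excess.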

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

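The log2 fold change of MYC lay between 4.99 and 5.37 under every alternative and stayed past the threshold. Of the other 108 named genes, all kept their call with DESeq2, RLE factors, no count filter, the length offset and protein-coding genes only (an alternative chosen after seeing the data), and no gene that passed changed direction in any alternative. With limma on log2(TPM + 1), 25 of 94 lost their call; without high MYC replicate 1 and 2, 7 and 6 did. That limma fit called 1990 genes, 1228 higher and 762 lower, among 11060 tested. With library totals 3157 genes were higher. Leaving out 1 library each, where the lone library was assumed to vary like the other group, gave 5062 to 9772 changed genes, 2711 to 5256 higher and 2351 to 4892 lower. The cause of these shifts was not tested. With the replicate number as a replicate block 10864 genes changed; replicates of the same number deviated together (correlation 0.514 over 11207 genes), but 2 pairs cannot show that the numbers pair the libraries. Of the 15 gene lists past camera, 0 passed with an estimated correlation (lowest adjusted p = 0.448). That setting rests on few residual degrees of freedom with 4 libraries, and lists with an estimate under the preset lost their call too. Ribosomal proteins (estimate 0.818) went from a camera p of 0.000592 to 0.588 before adjustment. Nucleotide synthesis (0.018) went from 0.000913 to 0.0913 at the same degrees of freedom. Estimated correlation thus accounts for part of the loss in a list such as ribosomal proteins, but the estimates rest on the same 4 libraries. Fry, which does not compare lists with other genes, passed 18 lists. Of these 12 were past camera too (not interferon response, oxidative phosphorylation and ribosomal proteins), and 6 were not: cholesterol synthesis, MYC network, osteoblast and bone, serine and one-carbon, TGF-beta and SMAD, and transcription elongation. Camera also gained the MYC network, which holds the induced MYC itself, with library totals and with the filter at 1 CPM, which lost the epithelial markers. It gained serine and one-carbon metabolism with no filter and, with osteoblast and bone genes, without high MYC replicate 1. Without low MYC replicate 2 it gained lysosome and autophagy and the histones, and lost epithelial markers and ribosomal proteins.

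The direction of 19 results of gene lists turned, and 0 of these passed in either setting, so no call is affected. For p53 targets the list medians there were 0.0 (RLE factors), -0.032 (no count filter), 0.027 (replicate block) and 0.02 (fry), and -0.197 to 0.175 on leaving out 1 library. With fry the antigen presentation, apoptosis, CTCF and cohesin, and NF-kB lists turned at unchanged medians of -0.01, -0.015, -0.009 and -0.137. On leaving out 1 library, medians ran from -0.235 to 0.115 for antigen presentation, -0.157 to 0.089 for apoptosis regulators, -0.122 to 0.046 for CTCF and cohesin, and -0.374 to 0.047 for histones. They ran from -0.136 to 0.218 for the circadian clock, 0.012 to 0.098 for E2F targets and -0.223 to -0.038 for NF-kB genes; camera's direction follows the mean and can turn while the median does not.

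The ratio of MYC peak numbers was 1.75, 1.83 and 1.65 at a -log10 q of at least 5 or 10 and a fold enrichment of at least 5. For H3K27ac it was 0.89, 0.845 and 0.807, and 1.01 after merging within 1 kb. With reciprocal 50% overlap, summits, a -log10 q of at least 10 and equal numbers of top peaks, 60.2, 74.1, 98.0 and 66.3% of low MYC peaks were kept. The reverse shares were 37.7, 44.0, 76.1 and 64.9%. For H3K27ac, reciprocal overlap, the stricter threshold and equal numbers gave 48.5, 92.7 and 67.5%, and in reverse 49.6, 97.6 and 74.4%. MYC peaks in H3K27ac regions were 66.8% in low and 68.7% in high MYC by summit, and 93.2 and 91.0% at the stricter threshold, so the order of the conditions turned there; with equal numbers high MYC had 88.7%. Super-enhancer-like clusters with a MYC peak were 30.3 and 55.0% with 5 kb stitching, 26.8 and 47.5% when ranked by width, and 52.3% in high MYC with equal MYC lists (chosen after seeing the data).

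On chromosome 2 alone 36 and 43 4C windows were called. Without windows within 100 kb, chromosome 2 took 25.2 and 21.9% of reads and the surrounding 1 Mb 5.0 and 4.0%. With at least 5 reads these shares were 28.4, 24.2, 8.9 and 6.8%; no called window had fewer reads, so that setting tests nothing for the calls. At a q under 0.01, 0.0% of low MYC windows held a MYC peak. The promoter comparison and its alternatives were not run. Peak lists and 4C tables carry no replicate error, which limits every difference drawn from them.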

Other observations

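All tests and named genes in this part were chosen after the data had been seen. Most snoRNAs, which guide the modification of ribosomal RNA, did not pass: of 292 tested, 34 rose (11.6%, against 23.4% of other genes), 1 fell and 257 did not pass (median log2 fold change 0.30). Of 45 snRNAs 9 rose (20%, against 23.2% of other genes) and 0 fell (median 0.51). SNORA80B went from 5.19 ± 0.20 to 9.34 ± 0.002 CPM (log2 fold change 0.85, edgeR adjusted p = 0.00176). Of 3009 long non-coding RNAs 157 rose (5.2%, against 26.3% of other genes) and 380 fell (12.6%, against 19.8%), with a median of -0.18. Camera adjusted p-values over 7 classes were 0.000204, 0.0026 and 0.0026, and with an estimated correlation the adjusted p-values were 0.301, 0.301 and 0.582. Many snoRNAs lie in introns of genes for the translation machinery, so their reads cannot be told from those of the host transcript, and short RNAs are poorly caught by this kind of library.

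Genes at MYC peaks were compared through the gene names that the 4C tables give for their listed windows, a partial annotation that covers 11512 tested protein-coding genes. Of 1945 genes with a high MYC peak in a listed window, 751 rose (38.6%) and 366 fell (18.8%). Of the other 9567 genes, 26.6% rose and 21.5% fell. Of 730 genes whose windows held a high MYC peak but no low MYC peak, 231 rose (31.6%) and 172 fell (23.6%), with a median log2 fold change of 0.03 in them and in the rest. The camera adjusted p was 0.0302 for all genes with a high MYC peak and 0.887 for those without a low MYC peak. With an estimated correlation the adjusted p-values were 0.301 and 0.923. Long genes have more windows and so more chances to hold a peak. Among genes with 1 listed window, 184 of 455 with a high MYC peak rose (40.4%), against 28.6% of the others.

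The first pattern weighed is the pair of narrow H3K27ac peaks on chromosome 8 at MYC, which share their start and end, or nearly so, across both lists; 4 H3K27ac peaks in the genome have identical edges in both. A candidate explanation is reads from extra copies of the MYC coding sequence, such as the inducible gene, placed by the aligner on the exons of the normal gene. Extra copies add reads to ChIP and input alike, which gives a high -log10 q at a modest fold enrichment. In low MYC both narrow peaks ranked within the top 0.0237% by -log10 q among peaks of like fold enrichment (rank 3 of 18064 and 3 of 12647), as extra copies would need. In high MYC the first peak was chosen for the highest -log10 q of its list. Its rank of 1 among 914 such peaks was therefore set in advance and is no test. The second peak ranked 1 of 3232 there. In the high MYC list the enrichment of these peaks was 15.8 and 6.70, which is not modest, so extra copies in ChIP and input alike do not by themselves account for the high MYC values. The upstream peak also ranked high (17 of 16082), so copies of the wider region stay open, and acetylation across the MYC gene itself cannot be told apart from reads of the inducible gene: the upstream peak had 0.146 of the enrichment of the strongest narrow peak in high MYC, but a single pooled list gives no spread.

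The second pattern is the longer MYC peak list in high MYC. Placement of the added peaks without regard to acetylated chromatin is argued against. Of peaks found in high MYC alone 68.0% overlapped H3K27ac of high MYC, while the highest of 1000 random shifts gave 4.06%. Peaks found in low MYC alone also exceeded their shifts, with 33.7% in H3K27ac of low MYC against at most 6.23%. The shifts do not mimic background reads that gather in acetylated chromatin, so peaks called from such background stay open. A deeper or more efficient ChIP stays open too. Of high MYC peaks with a -log10 q of at least 10, 23.9% were missing from the low MYC list, against 2.0% in reverse, which either more binding or more reads could give. Read depths of the ChIP libraries were not analysed here, so the binding of more MYC protein, which the design names, cannot be told apart from depth.

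The third pattern is the 4C calls on chromosomes other than 2, which were 45 of 81 in low MYC and 70 of 113 in high MYC. In high MYC 37.1% of them (exact 95% interval 25.9 to 49.5%) lay within 5 Mb of the longest stretch of their chromosome without any listed window or peak. The comparison set was 73337 of the 84096 listed windows of high MYC, of which 10.3% lay that near. In low MYC the shares were 33.3% (20.0 to 49.0%) and, for 58746 of the 68162 listed windows, 10.6%. Such stretches include centromeres, so repeat sequence that collects reads is a possible explanation for part of these calls. No biological explanation was tested for them.

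Across the 22 chromosomes other than 2 and Y, H3K27ac peaks per Mb and 4C reads per Mb went together, with Spearman correlations of 0.819 in low MYC and 0.807 in high MYC (Pearson 0.907 and 0.905). For MYC peaks the Spearman values were 0.598 and 0.438 (Pearson 0.646 and 0.352). In low MYC chromosome 8 was highest in both H3K27ac peaks (40.66 per Mb) and 4C reads (1956.82 per Mb), and chromosomes 13 and X were lowest in both. Both measures are divided by the same chromosome length. Copy number and mappable length of the chromosomes were not examined, so these correlations do not show that contacts follow acetylation. Chromosomes are not independent replicates, and no test was made.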
